A study of Mus musculus with 9 samples.

How the data were processed

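RNA from 9 samples of mouse mammary epithelial cell aggregates, 3 basal, 3 luminal and 3 mixed, was sequenced after extraction with a small-input kit and stranded mRNA library preparation. The authors' deposited table holds raw counts per gene name, as whole numbers with 1 column per library, together with the summed exon length in bases per gene name. Per the labels and the file headers, reads were processed with Trim Galore and Subread against the mouse build mm39 and counted by the authors with featureCounts 2.0.1 as read pairs over exons summed per gene name. Strand was not used although the libraries were stranded, so reads of overlapping antisense genes fall to either gene or to none, and reads with several alignments were not counted, so members of close gene families are undercounted. Beyond the name Subread, the aligner and its settings are not given in the sources used here, and neither is the annotation release. Gene positions were taken from the exon coordinates of the table itself, and the share of a gene's exon bases that another gene name also covers was computed from the same coordinates.

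The titles number the libraries of each group 1 to 3 and the descriptions number them differently, and the title numbers are used here. Same-numbered libraries of different groups were not more alike than others (r across genes of group-centred values from -0.17 to 0.20, and 4 of the 9 libraries correlated best with a library of their own number). The title numbers thus gave no sign of pairing, which does not exclude it, and the replicate block is only an alternative. The numbers in the descriptions were not checked in this way. No pair of libraries was a duplicate.

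Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passed filterByExpr with the 3 groups, libraries were scaled by the trimmed mean of M-values (TMM), and all 9 libraries were fitted together with the 3 groups as a factor, which left 6 residual degrees of freedom. The 3 pairwise contrasts were tested by edgeR's quasi-likelihood test (robust, two-sided), with Benjamini-Hochberg adjustment over the 18051 genes of a contrast and a threshold of 0.05. Log2 differences are given with the standard error of the fitted coefficient. For genes outside both pure groups, both contrasts had to share a sign and the larger p-value was adjusted. CPM are TMM-normalised without a pseudocount and are given as mean ± SD. Principal components used log2 CPM with a prior count of 2. A gene at 0 counts in a group is given by its CPM, with the limit set by 3 counts per library, and no fold is given for it.

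Before the data were examined, 34 gene lists were fixed from textbook knowledge, and the 33 with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 between genes, with adjustment over 99 tests. Camera with an estimated correlation is given where it ended a call, and for the calls that it kept. 1 of the lists and 2 genes that the rule names are not reported here. Of 654 list symbols 652 were measured and 590 tested. Named genes followed a rule fixed at the same time. It took the 8 highest and 8 lowest log2 differences per contrast among called genes with a mean of at least 10 CPM and no overlap between groups, up to 2 rising and 2 falling members per described list, 10 genes each above and below both pure groups, and a fixed set of keratin, adhesion and FGF pathway genes. Genes chosen after their values were seen are Klk10 in the fit with the code series, Cd74 and the transcripts that separate the 4 libraries of series A.

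The position of the mixed libraries is the median over genes of the mixed value minus the luminal mean, divided by the basal mean minus the luminal mean, in percent. List positions used members with a log2 difference of at least 1 between luminal and basal. On a simulated set, 100 genes were changed for each fold and each comparison, all in the same set. The test recovered 36% of 2-fold and 64% of 4-fold changes between groups of 3, with 4.76% false calls over both folds together. For genes outside both groups it recovered 16% and 61%, with 1.28% false calls over both folds together. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a test against a 1.5-fold change, fits of only the 2 groups compared, the title number as replicate block, other sets of genes for the position, fry, and each library left out in turn. Added after the data were seen were the code series as a term, which left 4 residual degrees of freedom, basal 2 and mixed 3 both left out, and basal 2 as the only basal reference.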

Results

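Mammary epithelium is built of luminal cells, which line the duct, and of contractile basal (myoepithelial) cells around them. RNA was sequenced from aggregates of wild-type mouse mammary epithelial cells that had been sorted by flow cytometry and had migrated in 80% Matrigel towards heparin sulfate beads of 100 to 150 µm soaked in FGF10. This is a growth factor that draws mammary epithelium forward as a group. The aggregates held basal cells alone, luminal cells alone or a 50% mixture of both, with 3 libraries of each kind. The stated purpose was to examine what basal and luminal cells contribute to collective migration at the mRNA level. The treatment label gives 56 h of migration and the sample titles give 55 h. No aggregate without FGF10 and no earlier time was measured, so the values compare kinds of aggregate and not a response to FGF10.

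The libraries held 17183990, 19096721 and 15585324 counts for basal 1, 2 and 3, 18729406, 17889034 and 16387086 for luminal 1, 2 and 3, and 18687186, 16382586 and 19164405 for mixed 1, 2 and 3. Of 54456 gene names, 20527 had 0 counts in every library and 18051 passed the filter on low counts and were tested. At this depth 3 counts correspond to 0.152 to 0.187 CPM (counts scaled to the size of their library), and a gene at 0 counts in a library may lie anywhere up to that level. Reads carried no molecular identifiers, so these limits cover counting error only. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, and every p-value measures the spread between these libraries only.

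The prefixes of the count table's column names fell into 3 code series that cut across the groups. Series A held mixed 1, 2 and 3 together with basal 2, series B held basal 1, basal 3 and luminal 1, and series C held luminal 2 and 3. The first principal component, with 43.6% of the variance, set luminal apart from basal and mixed libraries, and the second, with 27.4%, set basal 1 and 3 apart from the mixed libraries with basal 2 between them. Across genes, which are not independent replicates, basal 2 correlated with basal 1 and 3 at r = 0.927 and 0.936, while basal 1 and 3 correlated at 0.986. Luminal libraries did not divide by series in this way. Luminal 1 correlated with luminal 2 and 3 at 0.969 and 0.970, and luminal 2 and 3, which share a series, at 0.966. The mixed libraries, all of series A, correlated with each other at 0.922 to 0.948. A fit with the code series as a term compares luminal with basal within series B (luminal 1 against basal 1 and 3) and mixed with basal within series A (mixed 1 to 3 against basal 2). Each of these comparisons, and any list that passed only in it, rests on 1 library on the side of luminal 1 or basal 2. The spread is taken from all libraries of the fit. No series held both mixed and luminal libraries, so that contrast is reached in this fit only through basal. Gene counts of this fit, and the named genes whose calls ended in it, are given after those of each contrast. Signs shared by this fit and the pooled one are no independent evidence, because both rest on the same libraries. Of 44 list calls over the 3 contrasts 42 also passed in this fit, the other 2 are named, and 14 further ones passed only there, at the preset correlation. The 14 were not tested with an estimated correlation in this fit. In the pooled fit none of them passed with it either, which says little because they had not passed there at the preset correlation.

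**Figure D1:**
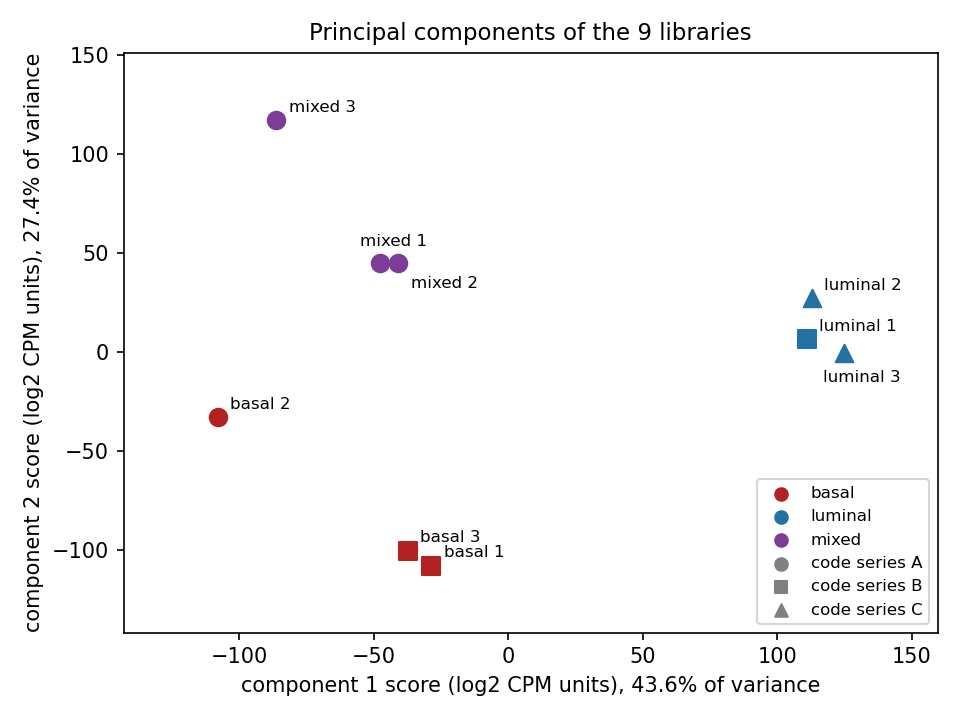
Scores of the 9 libraries on the first and second principal components of log2 CPM, which hold 43.6% and 27.4% of the variance. Colour gives the kind of aggregate and the marker shape gives the code series, and basal 2 lies apart from basal 1 and 3.

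Luminal aggregates differed from basal aggregates in identity, proliferation and matrix genes. Krt5, a keratin of basal cells (mm39 chromosome 15, 101615505 to 101621333), stood at 1842 ± 244 CPM in basal and 17.7 ± 5.16 CPM in luminal aggregates (SD, n = 3 each). The log2 difference was -6.70 ± 0.27 (SE, adjusted p = 7.4e-08). The proliferation marker Mki67 (chromosome 7, 135291513 to 135318090) stood at 229 ± 49.1 CPM in basal and 3.52 ± 0.998 CPM in luminal aggregates. Muc1, an apical mucin (chromosome 3, 89136364 to 89140688), went the other way, from 4.45 ± 0.68 CPM in basal to 242 ± 31.9 CPM in luminal aggregates. In all, 2304 genes were higher and 2595 lower in luminal than in basal aggregates, of which 1516 and 1940 differed by at least 2-fold.

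All 20 basal and myoepithelial markers fell in luminal aggregates, and the same 20 passed when adjusted over the list alone (median log2 -5.62, camera adjusted p = 8.2e-45, and adjusted p = 0.0052 with an estimated correlation). Pdpn, the surface glycoprotein podoplanin, differed by -8.42 ± 0.39, and Vim, the intermediate filament vimentin, by -8.14 ± 0.71, with 221 and 262 CPM in basal 1 and 3 and 695 CPM in basal 2. Acta2, smooth muscle actin, differed by -5.86 ± 0.49 and Trp63, the transcription factor p63, by -3.14 ± 0.22. Krt14 differed by -1.10 ± 0.25 (adjusted p = 0.0066) and stayed at 2114 ± 718 CPM in luminal aggregates, and within series B its difference of -0.86 did not pass (adjusted p = 0.18). Of 16 luminal keratins and pan-luminal markers 15 rose, and 15 also passed when adjusted over the list alone (median 1.45, adjusted p = 5.9e-14, and adjusted p = 0.018 with an estimated correlation). Krt8 rose by 0.75 ± 0.19, Krt18 by 1.88 ± 0.22 and the tight junction protein gene Cldn4 by 2.94 ± 0.24, while Cdh1, E-cadherin, differed by 0.27 ± 0.21 (adjusted p = 0.41).

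Luminal progenitor markers rose in 10 of 12 genes, with 11 up and 1 down when adjusted over the list alone (median 2.34, adjusted p = 6.5e-14, and adjusted p = 0.016 with an estimated correlation). Cd14 rose by 5.34 ± 0.29 and Plet1 by 2.84 ± 0.24. Of 12 hormone-sensing markers 8 rose and 1 fell, with 9 up and 1 down when adjusted over the list alone (median 1.45, adjusted p = 3.4e-05, adjusted p = 0.2 with an estimated correlation). Prom1 rose by 3.66 ± 0.47 and Greb1 by 3.06 ± 0.46, and Cited1 was lower at -2.15 ± 0.41. Of 10 milk protein and milk fat genes 6 rose and 2 fell (median 2.28, or 1.73 with genes at 0 counts set to their bound, adjusted p = 0.0047, adjusted p = 0.086 with an estimated correlation). Lalba, alpha-lactalbumin, stood at 0.178 ± 0.0702 CPM in basal and 82.1 ± 62.8 CPM in luminal aggregates, while the casein genes Csn1s1 and Csn3 differed by -4.24 ± 0.60 and -1.65 ± 0.25. The largest increases among abundant genes were those of Ccn5, a secreted matricellular protein (9.23 ± 0.34; chromosome 2, 163662781 to 163675066), Lalba, Dpep2, Lrg1 (7.12 ± 0.24), Pkib, Bglap3 and the acute-phase genes Saa2 and Saa1. For Dpep2, 21.9% of exon bases were shared with another gene, and its value is uncertain because reads were counted without strand. Among the largest decreases were those of Pdpn, Dsc3, Vim, Igfbp3 (-7.96 ± 0.51), Mylk (-7.92 ± 0.26), Dpysl3 and Serpinf1.

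Every one of the 28 cell cycle genes was lower in luminal aggregates, over all genes, when adjusted over the list alone and within series B (median -4.57, adjusted p = 9.3e-82, and adjusted p = 0.0052 with an estimated correlation). Mki67 differed by -6.03 ± 0.26 and the mitotic cyclin gene Ccnb1 by -5.53 ± 0.31. Of 21 cholesterol synthesis genes 19 fell and none rose, with 20 down when adjusted over the list alone (median -2.19, adjusted p = 6.0e-14, adjusted p = 0.093 with an estimated correlation). Stard4 differed by -3.17 ± 0.37. Glycolysis and hypoxia genes rose in 12 and fell in 1 of 22 (median 0.82, adjusted p = 4.8e-06, adjusted p = 0.15 with an estimated correlation). The glycolytic enzyme gene Aldoa differed by 2.74 ± 0.26, Adm by 3.41 ± 0.56 and Car9 by -1.32 ± 0.35. The 13 mitochondrially encoded genes took 1.05% of counts in luminal and 2.11% in basal aggregates, and 9 of them fell (median -0.88, adjusted p = 0.0014, adjusted p = 0.38 with an estimated correlation).

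Matrix genes were mostly lower in luminal aggregates. Of 21 basement membrane genes 14 fell and 1 rose (median -2.20, adjusted p = 9.6e-14, adjusted p = 0.086 with an estimated correlation). The laminin gene Lama1 differed by -7.14 ± 0.39, Col17a1 by -5.52 ± 0.40 and Lama5 by 0.67 ± 0.15. Of 22 interstitial matrix genes 14 fell and 2 rose (median -3.22, adjusted p = 7.7e-09, and adjusted p = 0.01 with an estimated correlation). Sparc differed by -7.70 ± 0.63 and Thbs1 by 1.32 ± 0.28, and Col1a2 stood at 5.16 ± 0.531 CPM in basal aggregates and at 0 counts in all 3 luminal libraries. Of 9 transcription factors and markers of epithelial-mesenchymal transition 7 fell and none rose (median -6.41, or -3.13 with bounds, adjusted p = 4.6e-05, adjusted p = 0.14 with an estimated correlation). Rac, Cdc42 and protrusion genes moved both ways, with 4 up and 5 down of 22 (median 0.12 but mean -0.53, adjusted p = 0.95). The actin bundler gene Fscn1 differed by -4.53 ± 0.54 and Cdc42ep3 by 1.90 ± 0.25. Apical-basal polarity genes rose in 9 and fell in 1 of 16 (median 0.86, adjusted p = 0.0028, adjusted p = 0.17 with an estimated correlation). The apical sialomucin gene Podxl rose by 1.66 ± 0.17, and Scrib was lower at -0.78 ± 0.16.

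Genes downstream of FGF and ERK signalling were divided. Of 21, 5 rose and 8 fell, with 5 up and 9 down when adjusted over the list alone (median -0.50, adjusted p = 0.06, and median -0.54 with adjusted p = 0.041 within series B). The ETS factor genes Etv4 (chromosome 11, 101660568 to 101676197) and Etv5 differed by -3.57 ± 0.26 and -2.58 ± 0.26 and the ERK phosphatase gene Dusp6 by -1.39 ± 0.17. In contrast, Ier3 differed by 1.68 ± 0.19 and Dusp4 by 1.55 ± 0.40. The FGF feedback inhibitor genes Spry2 and Spry4 differed by -0.50 ± 0.36 and -0.08 ± 0.56 (adjusted p = 0.36 and 0.94). Fgfr2, whose epithelial form binds FGF10, stood at 85.1 ± 28.6 CPM in basal and 43.1 ± 22.3 CPM in luminal aggregates (-0.98 ± 0.34, adjusted p = 0.053). Fgfr1 was higher in luminal aggregates by 0.74 ± 0.21 (adjusted p = 0.023, and 0.13 within series B). Transcripts of Fgf10 itself were at 0 counts in all 9 libraries. Of the 8 tested FGF ligands and receptors 1 rose and 1 fell (Fgf1, -2.31 ± 0.52).

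Notch pathway genes fell in 6 and rose in 2 of 15 (median -0.64, adjusted p = 0.0059, adjusted p = 0.086 with an estimated correlation). The ligand gene Jag2 differed by -4.98 ± 0.28 and the target gene Hey1 by 1.27 ± 0.20. Wnt pathway genes fell in 9 and rose in 3 of 20 (median -0.81, adjusted p = 0.044, adjusted p = 0.18 with an estimated correlation). Wnt10a differed by -6.15 ± 0.33, the secreted inhibitor gene Sfrp1 by -5.75 ± 0.45 and Wnt7b by 2.75 ± 0.27. Transforming growth factor beta and BMP genes rose in 10 and fell in 4 of 24 without passing as a list (adjusted p = 0.075), but passed within series B (median 1.13, adjusted p = 0.00055). Tgfb3 differed by 3.60 ± 0.20 and Bmp7 by -6.51 ± 0.30. The neuregulin genes Nrg2 and Nrg1 differed by -5.11 ± 0.32 and -4.28 ± 0.60 and Hbegf by 3.60 ± 0.40, within an epidermal growth factor family list of 8 up and 3 down of 17 (adjusted p = 0.34). Of 7 fibroblast markers 4 fell (median -4.51, or -3.28 with bounds, adjusted p = 9.5e-05, adjusted p = 0.086 with an estimated correlation), Fbln1 by -7.26 ± 0.39. Among immune markers Cd68 rose, from 3.10 ± 0.791 to 32.0 ± 15.9 CPM. Lyz2 and Cd74 fell, but stood at 15.4 and 27.3 CPM in basal 2 and at 1.88 CPM or less in basal 1 and 3. When adjusted over the list alone, 15 interstitial matrix and 11 mitochondrially encoded genes fell, and the counts up and down were 1 and 8 for mesenchymal markers and 5 and 5 for protrusion genes. They were 11 and 1 for polarity genes, 2 and 7 for Notch genes, 4 and 9 for Wnt genes, 13 and 4 for transforming growth factor beta and BMP genes and 1 and 2 for FGF ligands and receptors. The counts of milk, glycolysis, basement membrane, epidermal growth factor, fibroblast and immune lists were the same when adjusted over the list alone.

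These calls came from the quasi-likelihood test over all 9 libraries. Within series B 1280 genes were higher and 1227 lower, of which 1191 and 1195 were shared with the pooled calls, and 99.9% of the pooled calls of either direction kept their sign there. The calls of Krt14, Krt8 (0.35), Fgfr1, Dusp4 (1.01), Fgf1 (-3.02), Lama5 (0.51), Thbs1 (0.66), Scrib (-0.76), Car9 (-1.10), Lyz2 (-4.32) and Cd74 (-0.30) ended within series B, as did that of the Wnt list, whose median was -0.88 there and -0.81 in the pooled fit (adjusted p = 0.06). Against a 1.5-fold change 1257 genes were higher and 1628 lower. Library size scaling moved the median gene to -0.17 and the share of higher genes among the calls from 47.0% to 35.0%.

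Mixed aggregates had higher luminal markers and lower basal markers than basal aggregates. Kit, a receptor of luminal progenitors (chromosome 5, 75735576 to 75817382), stood at 499.8 ± 42.6 CPM in mixed and 43.5 ± 15.7 CPM in basal aggregates (log2 3.52 ± 0.29, adjusted p = 3.5e-05, 4.24 within series A). Muc1 differed by 5.20 ± 0.20 and Krt18 by 0.90 ± 0.21, while Krt5 was lower by a modest margin (-0.71 ± 0.21, adjusted p = 0.044, and 0.16 within series A). Etv4 stood at 13.7 ± 2.71 CPM in mixed and 69.3 ± 5.24 CPM in basal aggregates (-2.34 ± 0.25, adjusted p = 0.00018). In all, 1153 genes were higher and 1324 lower in mixed than in basal aggregates, and 778 and 901 of these differed by at least 2-fold.

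All luminal lists rose against basal aggregates. Pan-luminal markers rose in 12 of 16, and in all 16 when adjusted over the list alone (median 0.87, adjusted p = 4.2e-19, and adjusted p = 0.01 with an estimated correlation). Krt19 differed by 2.41 ± 0.20 and Krt8 by 0.63 ± 0.19. Luminal progenitor markers rose in 10 of 12 (median 2.22, adjusted p = 8.3e-26, and adjusted p = 0.0052 with an estimated correlation). Cd14 differed by 4.35 ± 0.28. Hormone-sensing markers rose in 7 of 12, and in 8 when adjusted over the list alone (median 1.24, adjusted p = 1.2e-10, adjusted p = 0.086 with an estimated correlation). Greb1 differed by 3.55 ± 0.47 and the prolactin receptor gene Prlr by 3.06 ± 0.23. Basal and myoepithelial markers fell in 8 of 20, and in 9 when adjusted over the list alone (median -0.81, adjusted p = 2.9e-06, adjusted p = 0.15 with an estimated correlation). Pdpn differed by -2.13 ± 0.26 and Cdh3 by -1.98 ± 0.22. Trp63 differed by -0.74 ± 0.21 (adjusted p = 0.035), and Krt14, Acta2, Vim and Cdh1 did not pass at -0.44 ± 0.25, -0.46 ± 0.39, -1.08 ± 0.51 and 0.14 ± 0.21. The largest increases were those of Pkib, Ccn5 (6.91 ± 0.32), Tmem213 (6.32 ± 0.48), Saa1, Saa2, Smoc1 (5.54 ± 0.61), Wfdc17 and Lalba. The largest decreases were those of Sema3b (-4.40 ± 0.52), Apobec1, Reln, Loxl3 (-3.90 ± 0.56), Clca3a2, Pcdhgc3, Krt23 (-3.58 ± 0.32) and Shisa8, of which Pcdhgc3 shared 66.8% of its exon bases with other genes.

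FGF and ERK response genes again moved both ways, with 2 up and 4 down of 21, and 2 up and 5 down when adjusted over the list alone (median -0.16, adjusted p = 0.16, and median -0.39 with adjusted p = 0.017 within series A). Etv5 differed by -1.78 ± 0.25 (adjusted p = 0.001), Dusp6 by -0.95 ± 0.17 (adjusted p = 0.0042) and Dusp4 by -1.82 ± 0.42, and within series A Etv4, Etv5 and Dusp6 differed by -2.45, -2.07 and -1.09. Fgfr2 was lower in mixed aggregates (-1.24 ± 0.34, adjusted p = 0.036), but within series A the difference of -0.65 did not pass (adjusted p = 0.44). Fgfr1, Spry2 and Spry4 differed by -0.38 ± 0.21, 0.27 ± 0.36 and -0.34 ± 0.56 without passing, and Fgfbp1, which releases FGFs from the matrix, rose by 1.31 ± 0.26.

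Basement membrane genes fell in 10 of 21, and in 13 when adjusted over the list alone (median -1.02, adjusted p = 1.5e-07, adjusted p = 0.17 with an estimated correlation). Lama1 differed by -2.73 ± 0.29 and Col7a1 by -2.01 ± 0.36. Interstitial matrix genes rose in 4 and fell in 2 of 22 (adjusted p = 1.0). Col8a1 differed by 2.61 ± 0.51 and Eln by -3.71 ± 1.11. The metalloprotease gene Adam12 and the inhibitor gene Timp3 rose by 2.51 ± 0.51 and 1.84 ± 0.33, within a protease list of 4 up and 6 down of 22 (adjusted p = 0.36). Timp3 shared 21.2% of its exon bases with another gene. Junction genes rose in 7 and fell in 2 of 27 (median 0.16, adjusted p = 0.013, adjusted p = 0.25 with an estimated correlation). Polarity genes rose in 4 of 16 (median 0.25, adjusted p = 0.0029, adjusted p = 0.17 with an estimated correlation). The tight junction protein gene Cldn1 differed by 1.69 ± 0.27 and Podxl by 2.70 ± 0.17. Transforming growth factor beta and BMP genes rose in 9 and fell in 2 of 24, with 12 up and 2 down when adjusted over the list alone (median 0.88, adjusted p = 0.00019, and adjusted p = 0.039 with an estimated correlation). Bmp2 differed by 4.29 ± 0.75, the BMP target gene Id1 by 3.88 ± 0.41 and Bmp7 by -2.71 ± 0.24. Cell cycle genes fell in 7 of 28, and in 10 when adjusted over the list alone (median -0.48, adjusted p = 0.0014, adjusted p = 0.4 with an estimated correlation), with Mcm5 at -0.94 ± 0.16 and Mki67 at -0.16 ± 0.21 (adjusted p = 0.65). Chemokine and inflammatory genes rose in 9 and fell in 2 of 23 (median 0.45, adjusted p = 0.0035, adjusted p = 0.2 with an estimated correlation). Mitochondrially encoded genes took 2.73% of counts in mixed aggregates and rose in 8 of 13 (median 0.72, adjusted p = 7.2e-06, adjusted p = 0.19 with an estimated correlation). Immune markers shifted as a list (median 1.76, adjusted p = 0.012, adjusted p = 0.41 with an estimated correlation) although none of the 9 passed singly. Cd74 stood at 26.3 to 36.4 CPM in the mixed libraries against the 27.3 CPM of basal 2. When adjusted over the list alone, the counts up and down were 5 and 4 for interstitial matrix genes, 4 and 8 for proteases and inhibitors, 10 and 3 for junction genes and 10 and 0 for mitochondrially encoded genes. Those of the progenitor, polarity, chemokine and immune lists stayed the same.

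Within series A, that is against basal 2 alone and with the spread taken from all libraries of the fit, 529 genes were higher and 324 lower, of which 451 and 278 were shared with the pooled calls. Of the pooled calls 100.0% of the higher and 98.6% of the lower ones kept their sign. The calls of Krt5 (-0.54), Trp63 (-0.47), Krt8 (0.68), Krt18 (0.89), Fgfr2, Dusp4 (-1.18), Reln (-4.12), Pcdhgc3 (-2.75), Col7a1 (-0.96), Eln (-3.14) and Bmp2 (4.24) ended within series A, as did that of the immune list, whose median was 0.38 there (adjusted p = 0.56). Lists that passed only within series A include milk genes (median 0.90, adjusted p = 0.0059), mesenchymal markers (-1.21, adjusted p = 0.0075) and cholesterol synthesis genes (-0.48, adjusted p = 0.00032). Without basal 2 the counts were 2709 higher and 2317 lower and without basal 3 they were 590 and 387. Library size scaling moved the median gene to -0.22 and the share of higher genes among the calls from 46.5% to 33.6%, and, against a 1.5-fold change 510 were higher and 388 lower.

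Mixed aggregates stood above luminal aggregates in basal, cell cycle and matrix genes, while luminal progenitor and hormone-sensing lists had medians near the luminal level. Krt5 stood at 1123 ± 36.5 CPM in mixed aggregates (log2 5.99 ± 0.26, adjusted p = 5.2e-07) and Mki67 at 205 ± 16.7 CPM (5.87 ± 0.26). Kit was higher in mixed aggregates than in luminal ones, at 499.8 ± 42.6 and 244 ± 55.3 CPM (1.03 ± 0.26, adjusted p = 0.015). Chil1, a secreted chitinase-like protein, was lower, at 566 ± 60.5 CPM against 11333 ± 2369 CPM (-4.32 ± 0.35). In all, 2749 genes were higher and 2560 lower in mixed than in luminal aggregates.

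Basal and myoepithelial markers rose in 18 of 20, and in 19 when adjusted over the list alone (median 5.01, adjusted p = 6.9e-43, and adjusted p = 0.0052 with an estimated correlation). Vim differed by 7.06 ± 0.69, Acta2 by 5.41 ± 0.48 and Trp63 by 2.40 ± 0.22. Krt14 differed by 0.65 ± 0.25 (adjusted p = 0.068). Pan-luminal markers rose in 1 and fell in 6 of 16 (median -0.41, adjusted p = 0.11). Krt18 differed by -0.97 ± 0.21, Cldn4 by -1.46 ± 0.23 and Krt19 by 1.76 ± 0.19, and Krt8 and Cdh1 by -0.12 ± 0.19 and -0.13 ± 0.21. Luminal progenitor markers had a median of -0.05 (adjusted p = 0.77) with 2 up and 3 down of 12, and hormone-sensing markers a median of 0.22 (adjusted p = 0.89) with 1 up and 2 down of 12. With the code series as a term the hormone-sensing list was higher in mixed aggregates (median 0.90, adjusted p = 0.025 at the preset correlation), but only 1 member rose and 1 fell, and the correlation estimated in the pooled fit was 0.34. Wfdc18 rose by 1.23 ± 0.31, Cited1 rose by 2.58 ± 0.42 and Prom1 was lower at -2.80 ± 0.45, while Prlr differed by 0.06 ± 0.21.

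All 28 cell cycle genes rose, also when adjusted over the list alone (median 4.23, adjusted p = 1.6e-89, and adjusted p = 0.0052 with an estimated correlation). So did 18 of 21 cholesterol synthesis genes (median 1.79, adjusted p = 1.5e-14, adjusted p = 0.086 with an estimated correlation). All 13 mitochondrially encoded genes rose (median 1.57, adjusted p = 2.5e-13, adjusted p = 0.086 with an estimated correlation). Glycolysis and hypoxia genes fell in 11 of 22, and in 12 when adjusted over the list alone (median -0.75, adjusted p = 8.4e-05, adjusted p = 0.18 with an estimated correlation). Vegfa differed by -1.93 ± 0.19. Interstitial matrix genes rose in 13 of 22 (median 3.06, adjusted p = 1.1e-11, and adjusted p = 0.0052 with an estimated correlation). Sparc differed by 6.64 ± 0.60. Fibroblast markers rose with them in 4 of 7 and none fell (median 4.68, or 2.34 with bounds, adjusted p = 0.00015, adjusted p = 0.086 with an estimated correlation). Basement membrane genes rose in 10 and fell in 2 of 21 (median 0.71, adjusted p = 9.7e-07, adjusted p = 0.18 with an estimated correlation). Mesenchymal markers rose in 7 of 9 (median 4.95, or 2.98 with bounds, adjusted p = 2.6e-05, adjusted p = 0.086 with an estimated correlation). Notch pathway genes rose in 9 and fell in 2 of 15 (median 1.28, adjusted p = 0.00018, and adjusted p = 0.041 with an estimated correlation). Jag2 rose by 3.70 ± 0.27. Wnt pathway genes rose in 6 and fell in 2 of 20 (median 0.46, adjusted p = 0.011, adjusted p = 0.13 with an estimated correlation), with Wnt10a at 6.32 ± 0.33. Of 21 FGF and ERK response genes 7 rose and 3 fell, with 9 up and 3 down when adjusted over the list alone (adjusted p = 0.28). Ccnd1, whose exon bases are shared at 23.3%, rose by 3.56 ± 0.35, Etv4 by 1.23 ± 0.25 and Etv5 by 0.80 ± 0.25. Dusp4 was lower at -3.37 ± 0.44 and Dusp6 differed by 0.44 ± 0.17 (adjusted p = 0.069). Fgfr1 was lower in mixed aggregates (-1.12 ± 0.22, adjusted p = 0.0035), and Fgfr2, Spry2 and Spry4 did not pass at -0.25 ± 0.34, 0.77 ± 0.36 and -0.26 ± 0.56. When adjusted over the list alone, the counts up and down were 2 and 4 for progenitor markers, 19 and 0 for cholesterol genes and 9 and 3 for Notch genes. Those of the pan-luminal, hormone-sensing, matrix, basement membrane, mesenchymal, fibroblast, mitochondrial and Wnt lists stayed the same.

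Of the 8 largest increases among abundant genes, 7 were secretory gland or gut transcripts abundant in series A and near 0 elsewhere, namely Bpifa2, Pip, Scgb1b27, Prol1, Dcpp1, Dcpp2 and Chia1. Bpifa2 stood at 364 to 667 CPM in the mixed libraries, at 340 CPM in basal 2 and at 0.108 CPM or less in the other 5. The remaining one was Adam12 at 7.13 ± 0.69 (chromosome 7, 133484928 to 133833875). The largest decreases were those of Dnajb13, Chil1, Acaa1b (-4.22 ± 0.46), Chrdl2 (-4.10 ± 0.30), Neat1, Chit1, Pdk4 and Bglap3 (-3.70 ± 0.37). Neat1, a nuclear noncoding RNA, differed by -4.06 ± 0.79 over all libraries but by 0.34 with the code series as a term. With the code series as a term 370 genes were higher and 121 lower, of which 349 and 96 were shared with the pooled calls, and 92.7% of the higher and 88.2% of the lower pooled calls kept their sign. The calls of the 7 gland or gut transcripts ended in that fit, as did those of Krt18 (-0.54), Fgfr1 (-0.50), Etv4 (1.49), Etv5 (0.56), Cldn4 (-1.31), Prom1 (-1.35), Dusp4 (-2.19), Wfdc18 (1.19), Dnajb13 (-2.18), Neat1, Chit1 (0.048) and Pdk4 (-2.72). Protease and chemokine lists passed only there (medians 0.94 and 0.68, adjusted p = 0.04 and 0.0085). Without luminal 3 the counts were 1594 higher and 1428 lower and without luminal 1 they were 1685 and 1629, and against a 1.5-fold change 1279 were higher and 964 lower.

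**Figure D2:**
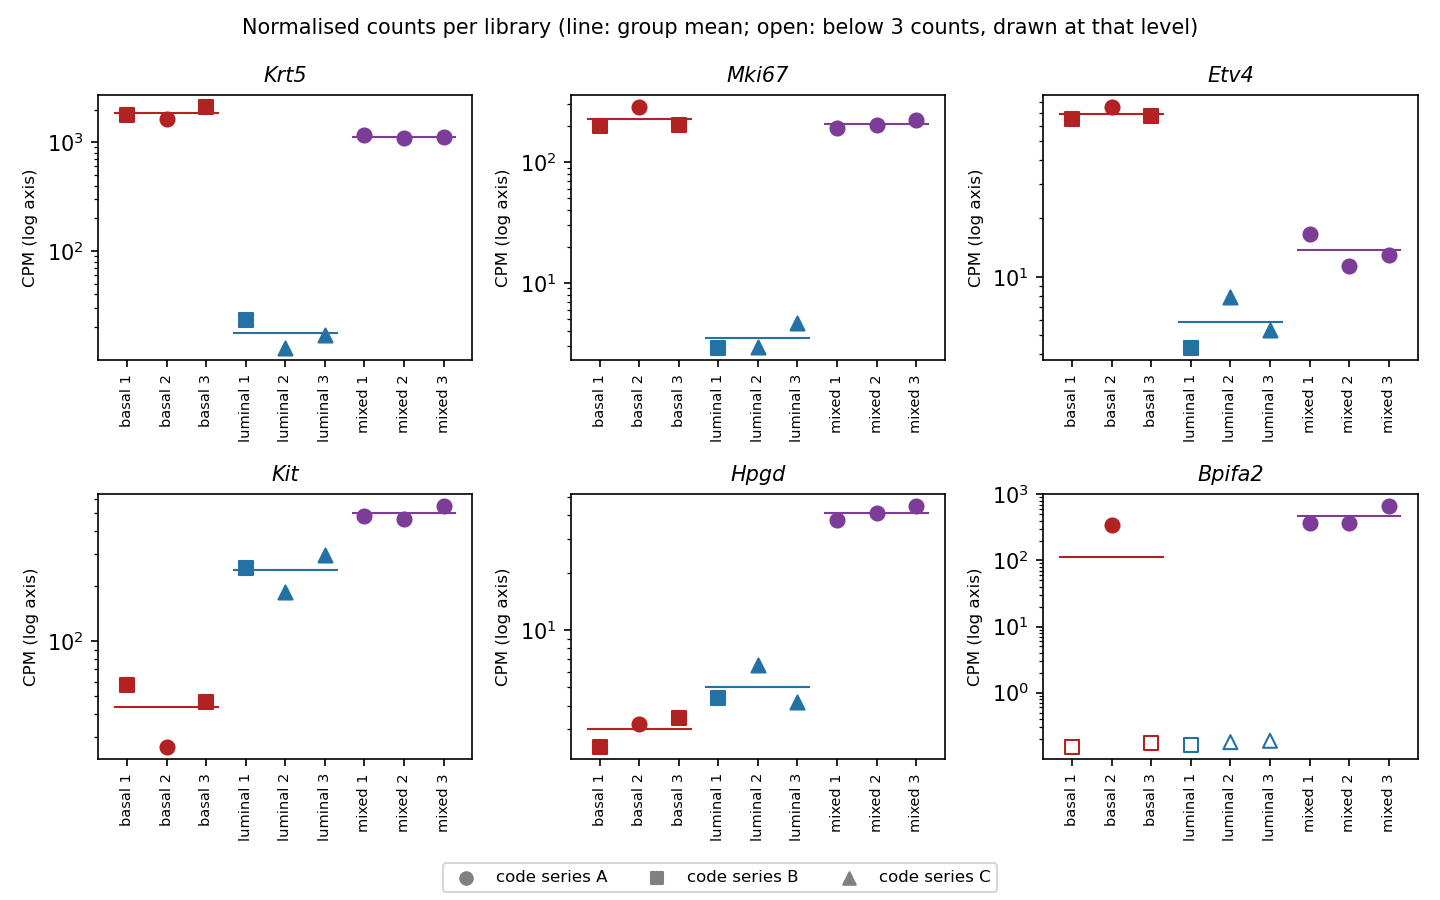
Normalised counts (CPM, log axis) of 6 genes in the 9 libraries, with lines at group means and marker shape for the code series. Etv4 was highest in the 3 basal libraries, and Krt5 and Mki67 were high in both basal and mixed libraries. Kit and Hpgd were highest in the 3 mixed libraries, and Bpifa2 was high in the mixed libraries and in basal 2.

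A mixture of cells that each kept the expression of the pure aggregates would lie between basal and luminal for every gene. In the mixed aggregates 40 genes stood above both pure groups and 61 below both. Hpgd, which inactivates prostaglandins (chromosome 8, 56747620 to 56774078), stood at 41.1 ± 3.45 CPM in mixed, 3.03 ± 0.528 in basal and 5.02 ± 1.31 CPM in luminal aggregates. The protease inhibitor gene Cst3 stood at 1217 ± 93.9, 257 ± 82.9 and 169 ± 59.7 CPM and Adam12 at 30.3 ± 2.67, 5.31 ± 1.43 and 0.200 ± 0.296 CPM in the same order. Snorc, Rtp4, Rbp7, Mgp, Fam25c, Ephx3 and Car2 completed the 10 largest above both. Clca3a2 (chromosome 3, 144502320 to 144525255) was lowest in mixed aggregates, at 21.8 ± 2.16 CPM against 292 ± 119 in basal and 161 ± 39 CPM in luminal aggregates. It was followed among the 10 largest by Dnajb13, Mtmr7, Aifm2, Slc4a11, Nek8, Fam20c, Fmnl3, Cyp4b1 and Tesk1, the last with 32.0% of its exon bases shared with another gene. Dnajb13 was low in all of series A, at 3.69 CPM in basal 2 and 1.47 to 3.38 CPM in mixed libraries. In basal 1 and 3 it stood at 17.3 and 16.7 CPM. Nek8 stood at 10.4 CPM in basal 2, 5.23 to 7.20 CPM in mixed libraries and 28.8 and 29.0 CPM in basal 1 and 3. Mtmr7, Aifm2, Slc4a11, Fam20c and Cyp4b1 stood in basal 2 near basal 1 or 3. Clca3a2, Fmnl3 and Tesk1 lay between those and the mixed libraries.

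The larger of the 2 p-values of each gene was adjusted over all genes, and at an unadjusted p under 0.05 the counts were 667 above and 1384 below. All 101 genes kept their sign on both sides with the code series as a term, but only Klk10, which is not among the 101, passed above both in that fit and none passed below. Part of the 101 still passed against basal in that fit, but this side rests on basal 2 alone. The luminal side is reached there only through basal. Simulated mixtures of the pure libraries gave at most 1 gene above and at most 3 below, but they carry no difference in code series between mixed and pure libraries. The replicate block gave 26 and 27 genes, and leaving out 1 library gave 7 to 777 above and 7 to 821 below, the highest without basal 2.

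Between the luminal mean at 0% and the basal mean at 100%, the mixed libraries lay at a median of 47.9 ± 0.943% (SD, n = 3) over 35 basal and luminal markers. The 50% mixture in the labels is a share of cells and not of RNA, and RNA content per cell was not measured. The SD covers the spread between the 3 libraries and not the choice of genes. For the groups named here, random lists matched in size, direction and abundance had medians of 60.6 to 68.0%. A percentile among 10000 such lists follows each value. It ranks the median over genes of positions averaged over the 3 mixed libraries, which can differ from the value printed. For hormone-sensing markers the ranked median was -4.89%, for luminal-high FGF and ERK response genes 71.9% and for glycolysis and hypoxia genes 90.3%. Luminal progenitor markers that were higher in luminal aggregates had a median of 2.83 ± 6.93% (percentile 0.07) and hormone-sensing markers one of 4.35 ± 16.1% (0.41). Their members lay on both sides of the luminal mean, with Kit and Wfdc18 above it and Cd14 (469 against 931 CPM) and Prom1 (35.6 against 248 CPM) below. The 10 luminal keratins and pan-luminal markers with a log2 difference of at least 1 lay at 59.0 ± 3.43% (35.6). This depends on that cut, because all 15 that passed in luminal against basal aggregates lay at 38.5 ± 6.71%. All 355 abundant genes higher in luminal aggregates by a log2 of at least 2 lay at 63.9 ± 1.11%. Basal-high FGF and ERK response genes lay at 28.3 ± 9.67% (4.8) and the 3 luminal-high ones at 81.3 ± 18.8% (61.6), and basal-high basement membrane genes lay at 32.3 ± 3.10% (2.09). Cell cycle genes lay at 70.8 ± 5.07% (56.8), as random lists do. Cholesterol synthesis genes lay at 84.9 ± 15.8% (95.4), luminal-high glycolysis and hypoxia genes at 85.4 ± 6.50% (98.8) and luminal-high milk genes at 89.7 ± 2.47% (93). With basal 2 as the only basal reference the cell cycle, cholesterol and glycolysis values were 61.7, 63.7 and 73.3%.

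**Figure D3:**
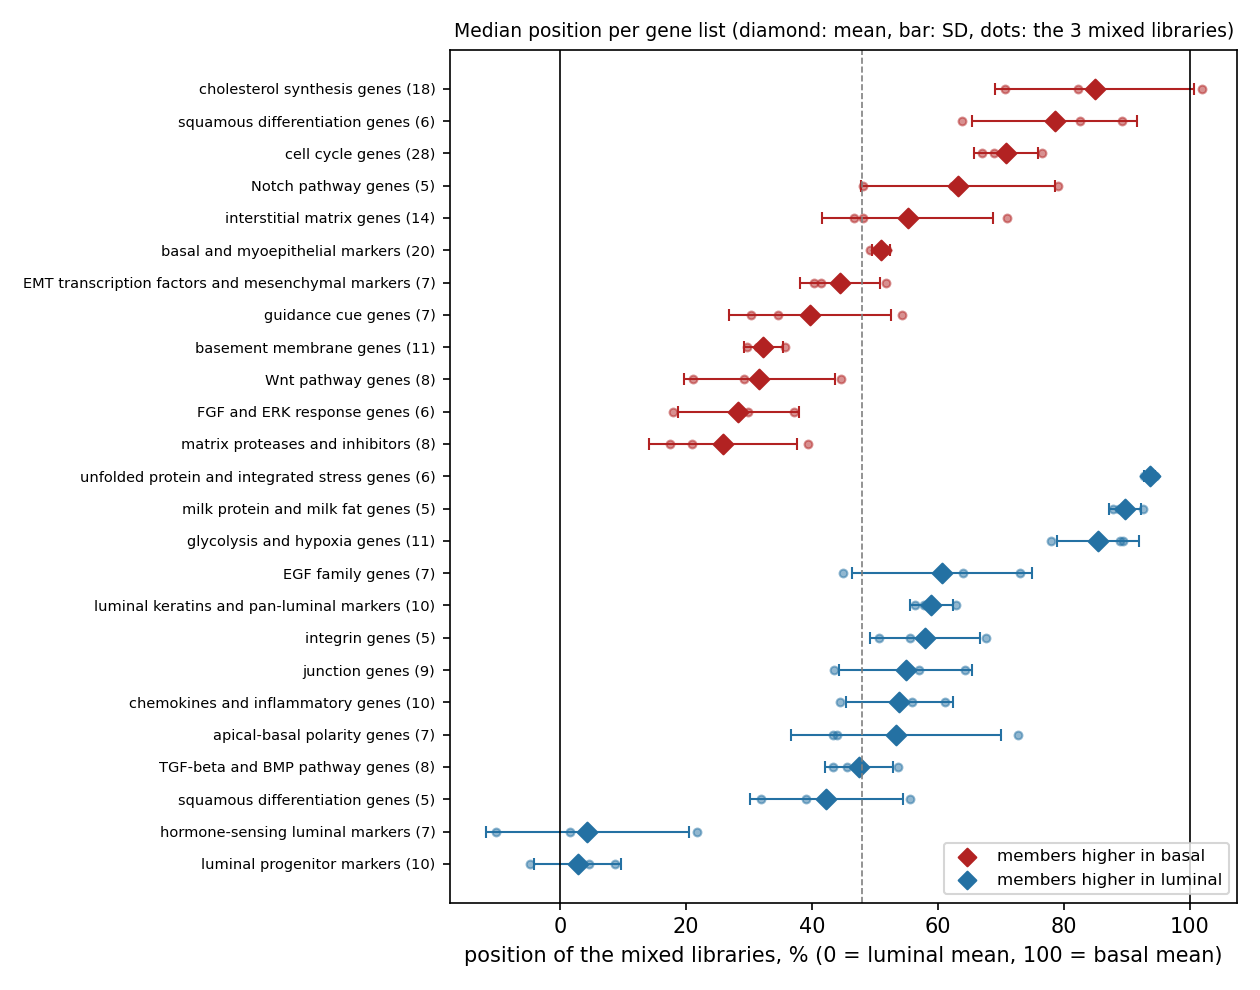
Median position of the mixed libraries between the luminal mean (0%) and the basal mean (100%) for most gene lists with at least 5 members, with a diamond at the mean, a bar for the SD and a dot for each of the 3 mixed libraries. The dashed line marks 47.9%, and luminal progenitor markers lie at 2.83% and cell cycle genes at 70.8%.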

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

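Tests chosen only after the data were seen were the code series as a term, basal 2 and mixed 3 both left out, and basal 2 as the only basal reference. The other scalings, the filter at 1 CPM and leaving out the 20 most abundant genes kept all gene counts within 1.5 times of those reported. Directions of the 392 named gene values were compared only where the value passed in the reported fit or in the alternative. Such values kept their direction under every alternative that could be computed except the code series as a term. Where no cause is named below, it was not tested.

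A test against a 1.5-fold change, which asks for larger differences, called 1257 higher and 1628 lower (luminal against basal), 510 and 388 (mixed against basal), 1279 and 964 (mixed against luminal), and 6 above and 11 below both pure groups. With the code series as a term, which leaves fewer libraries to each comparison, the counts were 1280 and 1227, 529 and 324, 370 and 121, and 1 and 0. In that fit 10 of the named values that had passed turned from higher to lower or the reverse, all for mixed against luminal. These were Bpifa2 (-3.56), Dcpp2 (-3.08), Neat1 (0.34), Chit1 (0.048), Lamb2 (0.30), Itga7 (0.36), Dll4 (0.52), Wnt7b (0.41), Epha1 (0.11) and Csf3 (0.20), none of them past the threshold there. A further 160 kept their direction but no longer passed. DESeq2 called 2340 lower for mixed against basal, and 206 above and 669 below both. limma-voom called 92 above both. Without a filter on low counts 2190 were lower for mixed against basal, and 357 above and 730 below both. The replicate block gave 26 above and 27 below both, and separate adjustment of the contrasts gave 186 and 512, where independent calls would give 176 and 188. Both contrasts share the mixed libraries and are not independent, so the latter counts cannot decide on chance.

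Leaving out each library in turn gave 1758 to 2563 higher and 1956 to 2815 lower for luminal against basal, 590 to 2709 and 387 to 2317 for mixed against basal (lowest without basal 3, highest without basal 2), 1594 to 3446 and 1428 to 3244 for mixed against luminal (lowest without luminal 3), and 7 to 777 above and 7 to 821 below both (highest without basal 2). Leaving out basal 2 and mixed 3 together gave 2570 and 2464 for mixed against basal, and 488 and 705 outside both. An estimated correlation lowered the lists past the threshold from 17, 13 and 14 to 5, 3 and 4. The basal share of 47.9% became 57.3 over the 904 abundant genes with a log2 difference of at least 2, 50.9 over basal markers, 38.5 over luminal markers, 45.6 by library size only, 44.9 against basal 2 and 45.7 to 49.6 with 1 pure library left out. Depth limits genes near 0.152 to 0.187 CPM, where 3 counts lie.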

Other observations

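Tests chosen only after the result was seen were those of a low basal share, of the code series in the basal libraries for luminal markers, and of expression that belongs to the mixed group.

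Several lists were not yet described. Unfolded protein and integrated stress genes rose in 7 and fell in 5 of 16 in luminal against basal aggregates (adjusted p = 0.1, but 0.00095 with a median of 0.89 within series B), with Xbp1, a factor of secretory cells, at 3.60 ± 0.18 and Sdf2l1 at -1.32 ± 0.26. Against luminal aggregates the same list fell in 8 and rose in 3 in mixed ones (median -0.57, adjusted p = 0.015, adjusted p = 0.39 with an estimated correlation), with Trib3 at -2.31 ± 0.26. Against basal aggregates it passed only within series A (median -0.49, adjusted p = 0.03). Squamous differentiation genes rose in mixed aggregates in 5 and fell in 2 of 21 against basal (median 0.69, adjusted p = 0.015, adjusted p = 0.45 with an estimated correlation) and rose in 9 and fell in 2 against luminal (median 1.56, adjusted p = 0.0029, adjusted p = 0.37 with an estimated correlation), with Krt4 at 2.91 ± 0.44 against basal. Integrin genes had 6 up and 4 down of 17 in luminal against basal aggregates (adjusted p = 0.36), Itgb3 at 2.32 ± 0.22 and Itga5 at -2.09 ± 0.26. Guidance cue genes had 5 up and 10 down of 31 (adjusted p = 0.61). The netrin genes Ntn1 and Ntn4 rose there by 2.48 ± 0.19 and 2.53 ± 0.26 and in mixed against basal aggregates by 2.63 ± 0.19 and 1.35 ± 0.25. Interferon response genes had 1 up and 3 down of 20 and p53 target genes 1 up and 2 down of 15 in luminal against basal aggregates. Interferon genes rose in 2 (median 0.64) in mixed against basal and in 5, or 8 when adjusted over the list alone, in mixed against luminal aggregates (median 1.28), and none fell. That list did not pass (adjusted p = 0.14 and 0.064) but did with the code series as a term (adjusted p = 0.00017 and 1.6e-07), where 1 member passed singly in each contrast. These values assume the preset correlation, and the correlation estimated in the pooled fit was 0.57 and 0.60 (adjusted p = 0.76 and 0.73 with it). No endothelial or pericyte marker of the 6 tested passed in any contrast by edgeR. When adjusted over the list alone, the counts up and down were 8 and 6 (luminal against basal) and 3 and 9 (mixed against luminal) for stress genes, 7 and 5 for integrin genes and 6 and 2 for squamous genes against basal, and the others stayed the same.

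Some further values are given without an explanation. Neat1 stood at 116 CPM in basal 2, at 233 to 312 CPM in the mixed libraries and at 1968 to 5452 CPM in the other 5. Haemoglobin genes stood above 2 CPM in all 4 libraries of series A, with Hbb-bs at 8.82 to 18.5 CPM against 0.0622 CPM or less elsewhere. The 5 of 13 mitochondrially encoded genes that were higher in basal than in luminal aggregates by at least 2-fold lay in mixed aggregates at 206 ± 6.78% of the way from luminal to basal, and at 154% with basal 2 as the reference.

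For the calls between groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split called 4899 genes (luminal against basal), 2477 (mixed against basal) and 5309 (mixed against luminal), and the highest other split called 0 in each, so 1 of the 10 splits gave as many. For gene lists the real splits called 17, 13 and 14 and the highest others 16, 13 and 13, so 1, 2 and 1 of the 10 splits gave as many. The other split of mixed and basal libraries with 13 lists set basal 1 with mixed 1 and 3, which does not follow the code series.

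Genes outside both pure groups were the first pattern weighed. Of 100 drawn splits of the 9 libraries, 3 gave as many genes as the real 101, the real split included. The others of these kept the luminal libraries (1503 genes) or the basal libraries (315 genes) together as the third group, so the count follows the structure of the samples. Most drawn splits put different kinds of aggregate into the same group, which widens the spread, so this share cannot decide on chance. Without basal 2, 777 genes lay above and 821 below both, and basal 2 was not used to choose them. Unlike the positions above, that of basal 2 was taken on log2 CPM with 0.5 CPM added. In these genes it lay at a median of 83.4% of the way from basal 1 and 3 to the mixed libraries (quartiles 56.2 and 102%). A difference between code series may therefore account for much of the excess on the basal side in that larger set, which includes all 101. With 1 basal library in series A, such a difference cannot be told apart from a deviation of basal 2 alone. In the 101 themselves, chosen with basal 2 in the basal group, the median was 25.2% on the same log2 scale. On the luminal side the code series and the mixed group cannot be told apart, because series A holds no luminal library, and an effect of contact between basal and luminal cells stays open and untested.

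Luminal progenitor and hormone-sensing markers with medians near the luminal level in mixed aggregates, and members on both sides of it, were the second pattern. Of 17 such genes 12 lay above the level that the basal share sets. Over all 17 the median log2 ratio to that level was 0.78 (quartiles -0.08 and 0.96). A low basal share of the mixed RNA would need basal markers near the luminal level too, and they lay at 50.9 ± 1.44%, which argues against it. The code series, as seen in basal libraries, shifted these genes by a median of -0.0023 in basal 2 against basal 1 and 3 (quartiles -0.73 and 0.68). This rests on 1 basal library, and because series A holds no luminal library the series and the mixed group cannot be told apart. An effect of basal cells on luminal genes stays open and untested.

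Secretory gland transcripts in 4 libraries were the third pattern. In all, 34 genes stood in every series A library at over 10 times the highest of the other 5, which was taken as at least 0.187 CPM. By the same rule 1 gene did the reverse. Of a list of 26 salivary gland genes 8 did so, against 0 of 18 pancreatic acinar genes, with Scgb2b26 at 87.1 to 237 CPM, Klk1 at 54.0 to 105 CPM and Smr3a at 38.1 to 85.6 CPM. The pancreatic genes Cpa1 and Ctrb1 were also detected in series A only, but at 0.54 to 1.60 CPM, too low for this rule. Of the 26 genes 2 (Aqp5 and Car6) exceeded 10 CPM in other libraries as well. Expression that belongs to the mixed group is argued against, because all 7 of the 7 transcripts seen first were also high in basal 2. RNA or reads from a salivary gland may have entered these libraries, but other glands with the same transcripts were not tested. Haemoglobin genes and the immune genes Cd74, H2-Aa, C1qb and Lyz2 were also among the 34, and their source was not tested.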
